A study of Mus musculus with 39 samples.

How the data were processed

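The data were deposited tables of transcript levels for 39 mouse samples of strain C57BL6/CBA. Per the labels' protocols, total RNA was purified with a Qiagen kit and libraries were made with the NEBNext Ultra kit. Cells were treated with 7 mM crotonic acid from day 16 to day 28, EpiLC were made in 2 days and PGCLC in 4 more days. Per the submitters' processing notes, the genome build was mm10 and the tools were Bowtie2, HISAT2, RSEM, R (3.4.2) and DESeq2; the notes give no order or role for each. Per the file headers, the values are FPKM, and the authors deposited them in 5 tables, 1 with 6 libraries of reprogramming cells, 1 with a granulosa cell library and 6 gPSC lines, 1 with the 21 libraries of germ cell induction, 1 with 2 ES, 1 granulosa cell and 1 fibroblast library, and 1 with a fibroblast library. The tables of reprogramming cells and of lines are rounded to 0.01 FPKM. Columns were matched to samples by stage, origin and number. The reprogramming table writes CS where the sample titles write CA, and the 3 ESC columns of the induction table and both fibroblast columns could be matched to their group, not to a numbered sample. Summed FPKM per library ranged from 386624 to 1067671. In the induction table, FPKM values of 17600 genes resolved into whole reads over coding length (within 0.001 reads), which gave totals of 6107304 to 25223994 assigned reads per library. These recovered reads served in an alternative test and in a check of counting noise. Between replicates, the mean chi-square per gene was 6.82 to 31.72, and 5.04 to 18.07 over genes of 1 to 2 FPKM, where counting error alone gives about 1. Genes with fewer reads were not examined for this. Depth of the other tables is unknown, and no interval that needs it is given. That table lists coding genes, so Xist, Meg3 and H19 are not analysed there. Symbols that a spreadsheet turned into dates were kept in the tests and left unnamed, and 99.4% of the IDs in the fibroblast table without symbols matched the GENCODE M21 annotation of GRCm38, which gave names and transcript lengths.

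Differences were tested within a table with limma 3.58.1 in R 4.3.3, as linear models on log2(FPKM + 1) with empirical Bayes moderation and a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over the genes tested. All libraries of a table entered the fit with group as the single term. Genes needed 1 FPKM in at least 2, 1 or 3 libraries of the reprogramming, line and induction tables, which left 13266, 13797 and 14059 genes. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1; "rose", "fell", "higher" and "lower" refer to such genes unless a list is named. There were 14 tested comparisons, 2 of them differences between steps by origin. Comparisons across tables were correlations across genes of log2(FPKM + 1), without a test, and there were 5. Gene lists, 27 in number with 12 to 26 genes, were tested where at least 5 genes passed the filter, by limma's camera with a preset correlation of 0.01 and again with an estimated correlation, and by fry, with adjustment over the lists of a comparison. Median differences of a list and its camera direction had the same sign unless stated, and camera sets a list against other genes whereas fry does not. Results of fry are given for crotonic acid alone. In the induction table they changed with the order in which groups entered the fit, and no check of this is given for crotonic acid. For day 28 against day 16 and for lines against granulosa cells they are not reported here. Genes were named by a rule set before the data were examined, as were groups, lists, comparisons and alternative settings. The rule took the 6 highest and 6 lowest called genes (4 for differences between steps) whose groups did not overlap and whose higher mean was at least 5 FPKM, without predicted genes or repeated symbols. Some genes that the rule took are not reported here. It added list members with the largest difference among those called, and 20 fixed genes and 4 Y-linked genes in each group.

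The test was checked on simulated data with 200 changed genes, 100 by 1.5 and 100 by 3 log2. For crotonic acid it called 79 and 98 of 100, with 3 false calls among the unchanged genes of 13266 in all. For lines against granulosa cells it called 84 and 99 with 2 false calls. For PGCLC by origin it called 93 and 100 with 10 false calls, and for the PGCLC step by origin 77 and 98 with 8. The simulated noise was normal and independent, with the same spread of a gene in each group, as the model assumes. The simulation therefore does not check unequal spread between groups or the assumed spread of the single granulosa cell library. Alternatives were a pseudocount of 0.1, no filter, median-ratio and quantile scaling, no trend, no minimum difference, the compared groups alone, the replicate number as a block, and each library left out. Added after the data were seen were voom on recovered reads and, for the reprogramming table, a correction of log2 levels for transcript length. Other computations used Python with numpy, pandas and scipy 1.17.1. Raw reads were not used here, so mapping and counting were not repeated.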

Results

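Transcript levels were measured by RNA sequencing in 39 mouse libraries of 14 groups, taken along a route from granulosa cells, the somatic cells that surround the oocyte, to pluripotent lines and germ cells. There were 2 libraries each of granulosa cells, embryonic fibroblasts, reprogramming cells at day 16 (also called XEN-like cells), reprogramming cells at day 28 with and without crotonic acid, and a female embryonic stem (ES) line. The lines obtained from granulosa cells are called gPSC lines, and each of the 6 (lines 2, 4, 10, 11, 15 and 16) gave 1 library. A second set held 21 libraries, 3 for each of 7 groups: a female ES line (ESC) and line gPSC4, both also as epiblast-like cells (EpiLC) and as primordial germ cell-like cells (PGCLC), and primordial germ cells (PGC) of E12.5 embryos. Levels are given as FPKM, fragment counts scaled to transcript length and library size, and differences as log2(FPKM + 1). Each library had between 11268 and 12979 genes at 1 FPKM or more. Libraries of the induction set held between 6107304 and 25223994 reads assigned to coding genes. The depth of the other libraries is unknown. Groups had 2 or 3 libraries, apart from the lines, and the p-values measure the spread between these libraries alone, since the labels do not say whether replicates came from separate cultures or animals.

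The first comparison asked whether granulosa cells or fibroblasts lay closer to the day 16 cells. Across 12651 genes, day 16 libraries had a mean Pearson's r of 0.826 with granulosa cell libraries and 0.722 with fibroblast libraries. The difference was 0.103, with an SD of 0.011 over the library pairs. These pairs reuse the same libraries, so that SD does not measure the spread between independent samples. The lowest r with granulosa cells, 0.809, exceeded the highest with fibroblasts, 0.743. Within the table that held both starting cells the values were 0.819 and 0.731. Granulosa cell transcripts remained to different degrees: Foxl2, a factor that maintains granulosa cell identity, stood at 22.4 ± 1.36 FPKM (SD, n = 2), against 35.0 and 27.7 FPKM in the granulosa cell libraries and 0.04 and 1.16 FPKM in the fibroblast libraries. Cyp11a1, the enzyme that opens steroid synthesis, stood at 1110 ± 53.4 FPKM in day 16 cells, against 5410 and 5340 FPKM in granulosa cells. Inha, a subunit of the hormone inhibin, was at 88.1 ± 14.5 against 2310 and 1490 FPKM, and Fshr, the receptor of follicle-stimulating hormone, at 0.01 against 2.18 and 1.63 FPKM. Col1a1, a fibroblast collagen, was at 69.5 ± 3.49 FPKM in day 16 cells and at 19.7 FPKM in each granulosa cell library. The libraries of the starting cells came from several tables and genes are not independent replicates, so no test was made. The difference was 0.068 without a minimum level and 0.178 among genes of at least 10 FPKM.

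**Figure D1:**
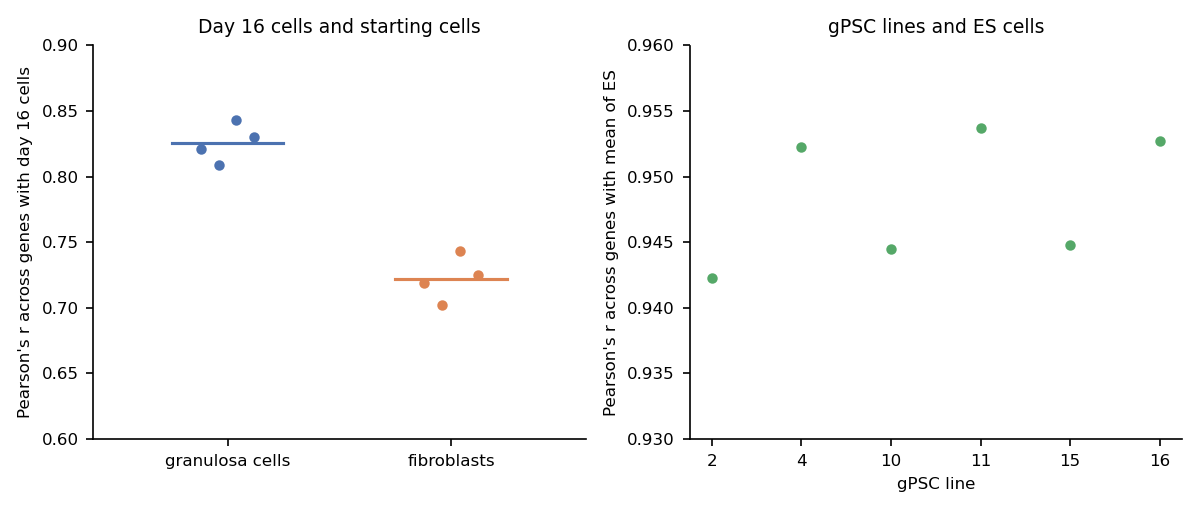
Left, Pearson's r across 12651 genes of each day 16 library with each granulosa cell or fibroblast library (points) and their means (lines), 0.826 and 0.722. Right, Pearson's r across 12742 genes of each gPSC line with the mean of both ES libraries, between 0.942 and 0.954. The y axes do not start at 0.

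Between day 16 and day 28 without crotonic acid, the cells gained epithelial, endodermal and some pluripotency transcripts, while Cyp11a1 and Hsd17b1 fell among the granulosa cell genes. Dppa5a, an RNA-binding protein of pluripotent cells, rose from 0.605 ± 0.516 to 18.5 ± 2.12 FPKM (SD, n = 2), and Sall4, a zinc finger factor of stem and germ cells, from 0.1 ± 0.0566 to 5.96 ± 0.0778 FPKM. Epcam, an epithelial adhesion molecule, rose from 10.4 ± 2.47 to 54.2 ± 6.12 FPKM, and the endoderm factor Sox17 (chromosome 1, 4490931 to 4497354) from 6.33 ± 3.07 to 26.6 ± 2.82 FPKM. Cyp11a1 fell to 449 ± 19.3 FPKM. Pou5f1, the central pluripotency factor (GRCm38 chromosome 17, 35506018 to 35510772), went from 0.09 ± 0.0424 to 0.645 ± 0.205 FPKM (0.59, short of 1 log2), and Gata4, Gata6 and Foxl2 differed by 0.12 log2 or less. The 6 highest called genes were Pgc (from 0.82 to 112 ± 14.2 FPKM), Myl3 (log2 difference 4.98), F2 (4.51), Car4 (4.45), Rhox5 (4.41) and Igsf1 (4.19). Among the lowest were S100a4 (−2.26), Hsd3b6, S100a6, Gsta2 and Prl2c2 (−1.98), of which Gsta2 and Prl2c2 have near-identical copies that make their levels uncertain.

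By fixed lists, 13 of 23 genes of extraembryonic and primitive endoderm rose and none fell between day 16 and day 28, among them Sox7 (2.33 ± 0.15, SE), Ihh (2.31 ± 0.25) and Lamb1 (2.09 ± 0.18). Adjusted over the list alone the count was 13 too. Of 17 epithelial genes 9 rose, with Cldn4 (2.65), Cldn6 (2.62) and St14 (2.23) next to Epcam (2.28). Of 12 core pluripotency genes 4 rose (Sall4, L1td1, Lin28a and Tdgf1), and of 12 naive pluripotency genes 4 rose (Dppa5a, Esrrb, Klf5 and Nr0b1). Cyp11a1 and Hsd17b1 (−1.45) fell out of 15 granulosa cell genes (median −0.07, camera adjusted p 0.017; adjusted p = 0.34 with an estimated correlation), and Igf2 rose to 665 ± 0.453 FPKM. In limma, 598 genes were higher and 110 lower out of 13266, and 1147 were called without day 16 replicate 2. That split depended on scaling: rescaling to median ratios gave 451 and 190, and quantile normalization 339 and 210, as the median over all genes moved from 0.15 to −0.02 under either. The camera test of limma gave an adjusted p of 0.00012 to the endoderm list (median 1.10, 0.95 over that of all genes; adjusted p = 0.34 with an estimated correlation) and 7.8e-06 to the epithelial list (median 1.18; adjusted p = 0.38 with an estimated correlation). The core list (median 0.57, 0.01 after quantile normalization) had an adjusted p of 0.0057 (adjusted p = 0.34 with an estimated correlation). Oxidative phosphorylation genes were lower as a list (median −0.40, −0.14 after quantile normalization, 1.7e-06; adjusted p = 0.38 with an estimated correlation). Replicate 1 and replicate 2 differed by a trend with transcript length in each of the 3 groups. Spearman's rho across 8789 genes was −0.70 at day 16, −0.46 at day 28 and −0.54 at day 28 with crotonic acid. The difference of day 28 from day 16 had a rho of 0.39, and 0.09 from day 16 replicate 2 alone.

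Cells at day 28 after continuous crotonic acid, a short-chain fatty acid given at 7 mM from day 16 to day 28, were compared with those without it. Pou5f1 stood at 22.7 ± 2.58 FPKM with the acid and 0.645 ± 0.205 FPKM without (SD, n = 2), a log2 difference of 3.85 ± 0.14 (SE, limma adjusted p 0.00086). Sox2, its partner factor, stood at 4.54 ± 0.212 against 0.655 ± 0.0354 FPKM, and Dppa5a at 45.7 ± 0.537 against 18.5 ± 2.12 FPKM. Sox17 was lower at 9.98 ± 1.76 FPKM (−1.34, adjusted p 0.049), as was the basement membrane gene Lamb1 at 31.9 ± 4.57 against 77.7 ± 2.23 FPKM. Nanog, at 1.27 FPKM with the acid, differed by 0.86, short of the minimum of 1 log2, and Gata4, Gata6, Col1a1 and Meg3 lay between −0.90 and −0.46, also short of it. These levels came from cell populations, and in the ES libraries Pou5f1 stood at 917 and 865 FPKM.

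The 6 highest genes with crotonic acid were Pou5f1, the intestinal and posterior factor Cdx1 (3.74, from 0.06 to 13.2 ± 1.97 FPKM), Trh (2.77), Nefl (2.33), Laptm5 (2.23) and Cyp2a5 (2.05), the last with near-identical copies. Among the 6 lowest, Mir1892, Snord58b, Snord99 and Snord42a were listed at 0 with the acid and at 19.9, 7.44, 5.65 and 5.24 FPKM without; these are very short RNAs, for which a level per kilobase is unreliable. The other pair was Ndufa4l2 (−2.50) and A2m (−2.34). Of 12 core pluripotency genes 5 rose and 0 fell, over all genes and adjusted over the list alone, including Utf1 (2.07) and Dnmt3l (1.24). Of 12 naive genes 2 rose, Dppa5a (1.27) and Zfp42. Of 23 endoderm genes 8 fell and 0 rose, including Sox7 (−1.83) and Ihh (−1.62). Kit (−1.39), Kdr (−1.28), Cd34 (−1.44), Snai1 (−1.34), Igf2 (−1.15) and the mesothelial gene Upk3b (−1.08) fell too. Zscan4f, of the two-cell-like genes, was at 1.15 ± 0.113 FPKM with the acid and listed at 0 without. None of 26 genes that write, read, erase or supply crotonyl and other acyl marks was called (median −0.01 with camera's direction upward, camera adjusted p 0.43).

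In limma 113 genes were higher and 159 lower with crotonic acid out of 13266, and 2872 had an unadjusted p under 0.05. The excess of lower genes depended on scaling, at 122 higher and 119 lower after rescaling to median ratios and 134 and 132 after quantile normalization. When any 1 of the 4 libraries was left out, which leaves 1 library in a group, far fewer genes were called, so the count rests on having both replicates. Of 28 genes named above as called, 23 lost the call in at least 1 of these fits, among them Sox2, Dppa5a and Sox17, while Pou5f1 was called in each with a difference between 3.72 and 3.98. The core pluripotency list was higher (median 0.88, camera adjusted p 5.7e-07; adjusted p = 0.22 with an estimated correlation), and so was the naive list (median 0.20, 0.0058; adjusted p = 0.26 with an estimated correlation). The endoderm list was lower (median −0.61, 2e-05; adjusted p = 0.23 with an estimated correlation), as was the proliferation list (median −0.38, 4.7e-05; adjusted p = 0.27 with an estimated correlation). The lists of gonadal somatic, imprinted and fibroblast genes were lower and those of glycolysis, fatty acid oxidation and p53 higher at adjusted p between 0.0016 and 0.0058, and 0 of the 10 calls held with an estimated correlation. The fry test, which asks whether a list's own genes move one way on balance, gave the core list an adjusted p of 9.9e-05 and the endoderm list 0.011. It does not set a list against other genes, and its dependence on the order of groups in the fit was not checked here.

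**Figure D2:**
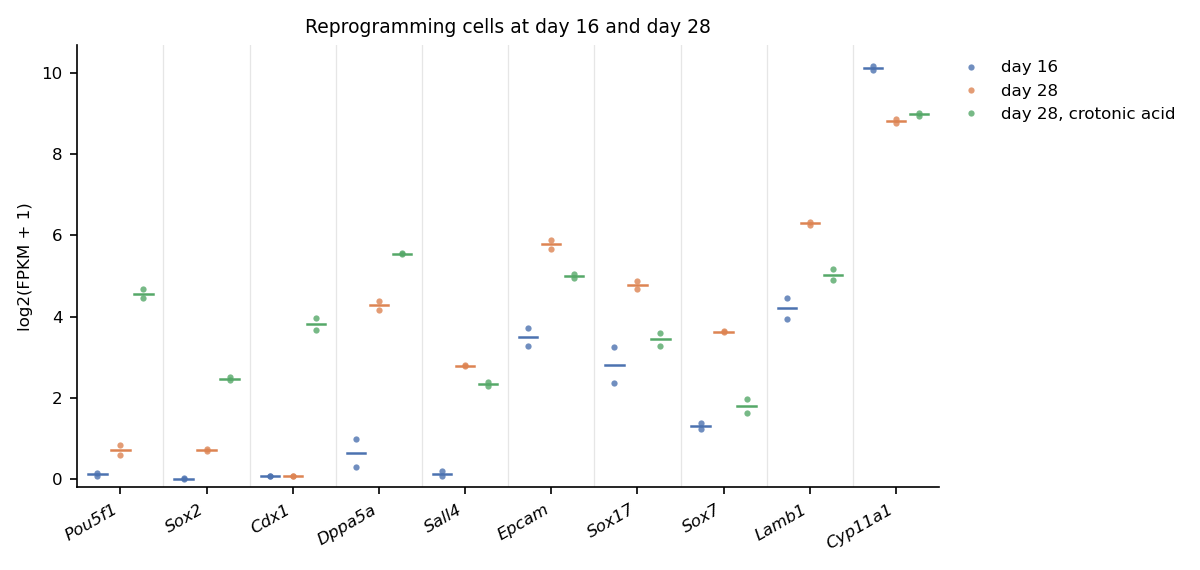
Level of 10 genes in the reprogramming cells as log2(FPKM + 1); points are libraries (n = 2 per group) and short lines are group means. Pou5f1 and Cdx1 stood apart with crotonic acid, and Sox17, Sox7 and Lamb1 rose by day 28 and were lower with the acid.

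The 6 gPSC lines were compared with the granulosa cells of the same table, a single library that was assumed to vary as the lines did and gives no replicate check. Pou5f1 stood at 1270 ± 113 FPKM in the lines (SD, n = 6) and at 1.7 FPKM in granulosa cells, Nanog at 191 ± 28.9 against 0.26 FPKM and Sox2 at 151 ± 17.9 against 0.09 FPKM. Dppa5a had the largest rise, from 0.41 to 1440 ± 148 FPKM. The granulosa cell program was lost: Cyp11a1 stood at 4.58 ± 1.87 against 5410 FPKM, Inha at 1.79 ± 0.463 against 2310 FPKM, and Foxl2 at 0.122 ± 0.0893 against 35.0 FPKM. Col1a1 went the other way, from 19.7 to 609 ± 204 FPKM, as did the fibroblast surface gene Thy1, from 2.03 to 178 ± 48.2 FPKM. The 6 highest were Dppa5a, Pou5f1 (8.87), Tdgf1 (8.08), Utf1 (7.76), Tdh (7.52) and L1td1 (7.31). The 6 lowest were Hsd3b1 (−10.41), Aldh1a1 (−9.99), Cyp11a1 (−9.98), Inha (−9.71), Sfrp4 (−9.45) and Akr1cl (−9.23). Sall4 (5.85), Cdh1 (to 77.4 FPKM), Dppa3 (3.79) and Ddx4 (2.56) rose, and Gata4 (from 130 FPKM), Star (−6.62), Nr5a1 (−5.88) and Gata6 (−2.27) fell. Fshr was at 2.18 FPKM in granulosa cells and listed at 0 in the lines. Meg3, an imprinted transcript that is silenced in some reprogrammed lines, was at 99.2 ± 24.6 against 130 FPKM (−0.42, not called), and Xist, which coats the inactive X chromosome, fell from 23.0 FPKM by 2.62 log2.

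By list, 14 of 14 core and 16 of 17 naive pluripotency genes rose in the lines, 17 of 19 granulosa cell genes fell, and 24 of 24 proliferation genes rose (median 2.61; Ccne1 4.74, Mcm5 4.11, Cdc20 3.18). The counts adjusted over the list alone were the same. Of 22 fibroblast genes 18 rose and 2 fell (median 2.78), of 13 two-cell-like genes 10 rose, of 19 glycolysis genes 12 rose, and of 20 fatty acid oxidation genes 6 fell, Cpt1a the most (−3.60). H19 (6.96) and Igf2 (6.02) led 11 of 23 imprinted genes that rose; both are abundant in fibroblasts, H19 at 2910 FPKM in 1 library and Igf2 at 2230 FPKM in the other. Of 17 genes of the fetal gonad's somatic cells 10 fell and 3 rose, and of 21 telomere maintenance genes 10 rose. In limma 3002 genes were higher and 2442 lower out of 13797. That balance depended on scaling, at 2789 and 2693 after rescaling to median ratios and 2586 and 2648 after quantile normalization. The camera test gave the core list an adjusted p of 3.8e-09 (adjusted p = 0.33 with an estimated correlation), the granulosa cell list 3.8e-09 (adjusted p = 0.26 with an estimated correlation) and the proliferation list 6.6e-10 (adjusted p = 0.36 with an estimated correlation). Of 20 list calls 0 held with an estimated correlation, the naive list coming closest (median 4.68; adjusted p = 0.071 with an estimated correlation).

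How far the lines resembled ES cells was described without a test, since lines and ES libraries lay in different tables. Across 12742 genes, Pearson's r with the mean of both ES libraries was 0.954 for line 11, 0.953 for line 16, 0.952 for line 4, 0.945 for line 15, 0.945 for line 10 and 0.942 for line 2, against 0.996 between the ES libraries. Line 4, the one taken into germ cell induction, ranked 3. The change from granulosa cells to the lines and that from granulosa cells to ES cells, with no library shared, had r 0.939 across 13268 genes (SD 0.007 over the lines). Pou5f1 lay between 1160 and 1470 FPKM in the lines and at 917 and 865 FPKM in ES cells. Dppa3, a maternal and germ cell factor (chromosome 6, 122626410 to 122630272), was at 4.51 FPKM in line 10 and 9.27 FPKM in line 2, at 21.5 to 30.3 FPKM in the other lines, and at 23.6 and 22.9 FPKM in ES cells. Zscan4c, a marker of two-cell-like cells with near-identical copies, lay between 4.57 and 11.2 FPKM in the lines and at 88.9 and 79.1 FPKM in ES cells. Col1a1 was high in both, at 402 to 902 FPKM in the lines and 641 and 597 FPKM in ES cells. Over 28 genes abundant in fibroblasts and low in granulosa cells, the lines stood at a median of 11.4% to 22.6% of the fibroblast level and each ES library at 13.4%. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together reached 2.26 to 4.54 FPKM in the lines and 6.71 and 6.23 FPKM in the female ES line, against 0.07 FPKM or less in granulosa cells and 0 and 22.5 FPKM in the fibroblast libraries.

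**Figure D3:**
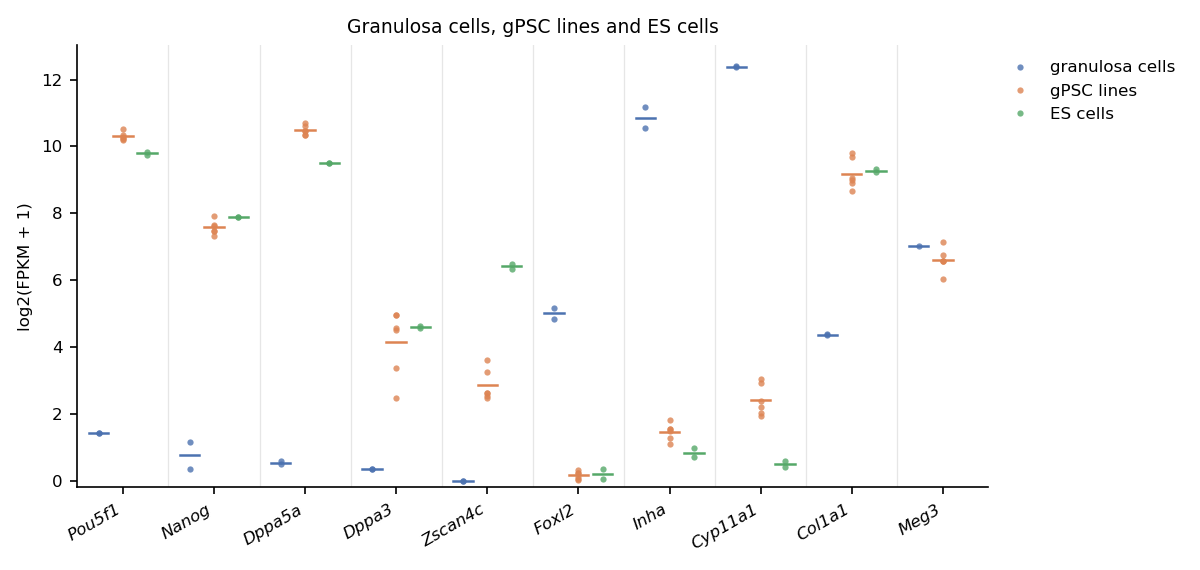
Level of 10 genes in granulosa cells, the 6 gPSC lines and ES cells as log2(FPKM + 1); points are libraries and short lines are group means, and libraries come from separate tables. Meg3 is drawn for the lines and 1 granulosa cell library. Each line lay above both ES libraries in Pou5f1 and below both in Zscan4c, and ES cells lay within the range of the lines in Nanog.

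At each stage of induction the gPSC4 origin was set against the ESC origin. As stem cells both had the pluripotency factors at like levels: Pou5f1 stood at 238 ± 1.23 and 238 ± 7.57 FPKM, Nanog at 998 ± 131 and 986 ± 73.3 FPKM, and Sox2 at 28.1 ± 1.13 and 30.9 ± 0.637 FPKM (SD, n = 3). Sfrp2, a secreted Wnt modulator, was the 1 gene called out of 14059, lower in gPSC4 at 8.66 ± 1.73 FPKM (−1.13 ± 0.18 SE, limma adjusted p 0.027). Dazl, a germ cell RNA-binding protein, was lower by 0.75 log2 at adjusted p 0.027 without reaching 1 log2. The count at an unadjusted p under 0.05 was 592. Voom on recovered reads called the same gene, which lost its call with only both groups in the fit. Without gPSC4 replicate 3 the count was 3, and without any other library of these groups it was 0. Fibroblast genes were lower as a list in gPSC4 (median −0.32, camera adjusted p 9.2e-07, 0.0012 with an estimated correlation). The 28 fibroblast-abundant genes moved with them, at a mean of 3.13% of the fibroblast level in gPSC4 and 3.77% in ESC, as did the summed Y-linked level, at 3.72 and 5.45 FPKM. Glycolysis (median 0.08, 1.2e-07) and epithelial genes (median 0.13, 0.0012) were higher and both held with an estimated correlation at 0.012. Late germ cell genes were lower (median −0.11, 0.018; adjusted p = 0.34 with an estimated correlation). Library pairs of the 2 origins had a mean r of 0.990 across genes, those within ESC 0.993 and within gPSC4 0.989.

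As EpiLC, gPSC4 had 6 genes higher and 4 lower than ESC. The named ones were Tmem86a (1.18), Fam81a (1.17) and the hormone precursor Trh (−1.10, 24.9 ± 2.65 against 54.3 ± 5.57 FPKM). All 3 lost the call with voom, with both groups fitted alone and in at least 1 fit with a library left out. Fgf5 stood at 117 ± 9.18 and 175 ± 3.31 FPKM without being called, and 1202 genes had an unadjusted p under 0.05, while voom called 2. Without gPSC4-EpiLC replicate 2 the count was 4, without ESC-EpiLC replicate 1 it was 5 and without ESC-EpiLC replicate 2 it was 6. Glycolysis genes were higher as a list (median 0.20, camera adjusted p 1.2e-10, 0.0094 with an estimated correlation) and targets of TGF-beta and BMP lower (median −0.25, 0.00076, 0.0094 with an estimated correlation). As PGCLC, 13 genes were higher and 31 lower, led by Chst11 (1.63), Msmp (1.37), Zfp931 (1.34), Cd34 (1.14) and Vhl (1.12) and by Fam89a (−3.21), Iba57 (−2.10), Bag1 (−2.03), Nsmce4a (−2.02), Cited2 (−1.80) and Phykpl (−1.74). Of these 11 calls, 8 were lost with voom, 11 with both groups fitted alone and 8 in at least 1 fit with a library left out. The germ cell genes Dppa3, Dazl, Ddx4, Prdm1 and Tfap2c differed by 0.11 log2 or less. Glycolysis genes were again higher (median 0.16, 9.2e-07; adjusted p = 0.059 with an estimated correlation). The PGCLC count rested on the choice of method, at 22 with voom, 88 with the replicate number as a block and 0 with both groups fitted alone. It was 157 without gPSC4-PGCLC replicate 3, 117 without ESC-PGCLC replicate 1 and 29 without ESC-PGCLC replicate 3. Groups did not overlap for 1689 of 14059 genes, where chance gives 10%.

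The step from stem cells to EpiLC, 2 days in bFGF and Activin A, moved both origins from the naive toward the primed state of the epiblast. Fgf5, the classical marker of the primed epiblast, rose to 175 ± 3.31 FPKM from ESC and from 1.47 ± 0.841 to 117 ± 9.18 FPKM from gPSC4 (SD, n = 3). The DNA methyltransferase gene Dnmt3a rose to 358 ± 8.16 and 378 ± 11.4 FPKM, and Dnmt3b from 45.7 ± 3.85 to 564 ± 29.2 and from 40.7 ± 8.41 to 522 ± 25.2 FPKM. Nanog fell from 986 ± 73.3 to 22.5 ± 7.08 and from 998 ± 131 to 24.4 ± 6.92 FPKM, and the naive factor Tfcp2l1 from 483 ± 36.0 to 4.84 ± 1.19 and from 529 ± 88.6 to 5.78 ± 1.44 FPKM, while Pou5f1 stayed within 0.33 log2. From ESC the 6 highest were Car4 (7.39), Tmem54 (6.54), Fgf5 (6.47), Enpp2 (5.40), Pim2 (5.38) and Dnmt3a (5.08), and the same 6 headed the step from gPSC4. The 6 lowest from ESC were Tfcp2l1 (−6.39), Jam2 (−6.39), Ubd (−6.33), Tcl1 (−6.12), Mras (−6.04) and Tbx3, and Tfcp2l1, Jam2, Ubd, Tcl1 and Tbx3 were also among the lowest from gPSC4. Prdm14 (−4.18 and −4.28), Tfap2c (−3.30 and −3.47) and Prdm1 (−1.78 and −1.70) fell too, and Col1a1 fell from 135 ± 1.63 to 4.99 ± 0.934 and from 104 ± 6.95 to 3.65 ± 0.489 FPKM.

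Of 17 naive genes 15 fell from each origin, and of 15 formative genes 13 rose from ESC and 12 from gPSC4. Early germ cell genes fell in 11 of 16 from each origin, fibroblast genes in 17 and 15 of 21, and epithelial genes rose in 9 of 17 from each, Cldn6 by 4.45 and 4.18. The 28 fibroblast-abundant genes went from 3.77% to 0.448% of the fibroblast level from ESC and from 3.13% to 0.332% from gPSC4, and the Y-linked level went from 5.45 to 1.08 and from 3.72 to 0.61 FPKM. Of 15 meiosis genes 6 and 5 rose, and the piRNA gene Mael rose too (3.44 from gPSC4). These 6 lists passed the camera test of limma from both origins with the preset correlation, at adjusted p between 3.6e-16 and 0.0065, and with an estimated one, at 0.021 or less. Late germ cell genes were higher (0.0077 and 0.0055; adjusted p = 0.125 and adjusted p = 0.105 with an estimated correlation) and oxidative phosphorylation genes lower (0.034 and 0.0094; adjusted p = 0.26 and adjusted p = 0.16 with an estimated correlation). In limma 1355 genes rose and 1592 fell from ESC, and 1422 rose and 1452 fell from gPSC4. Across 13912 genes the changes of both origins had r 0.934, against 0.839 to 0.865 for differences of single libraries.

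**Figure D4:**
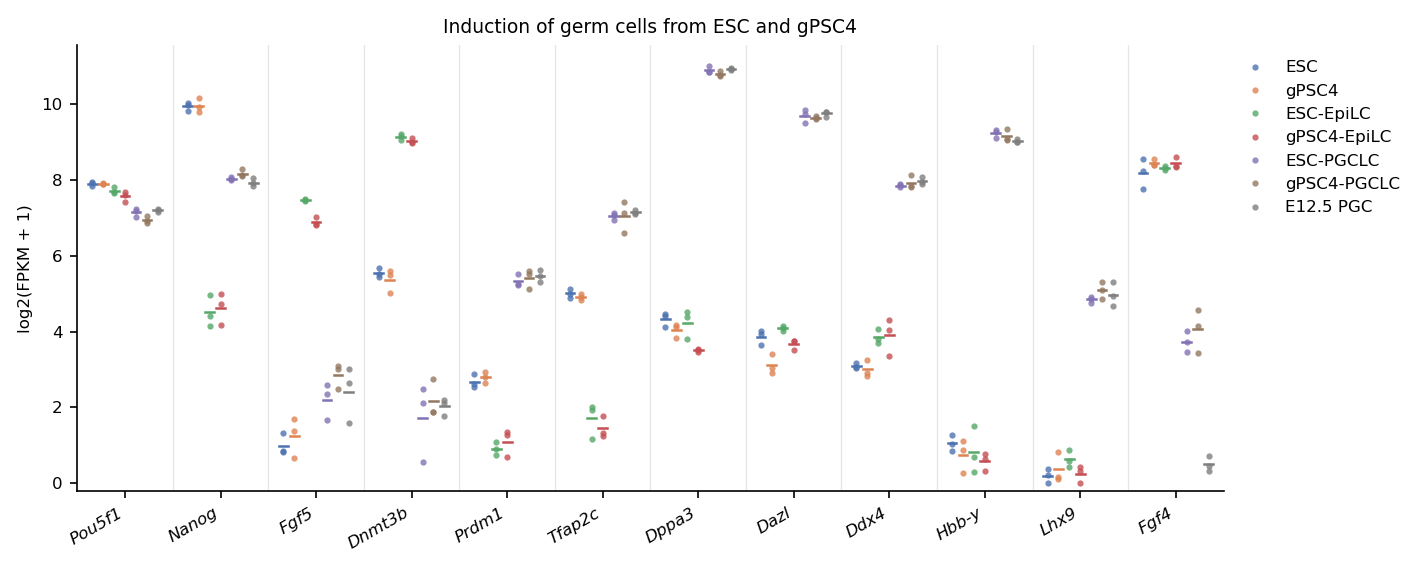
Level of 12 genes in the 7 groups of the induction set as log2(FPKM + 1); points are libraries (n = 3 per group) and short lines are group means. PGCLC of both origins and PGC lay together for 11 of the genes, and Fgf4 was higher in PGCLC.

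The step from EpiLC to PGCLC, 4 days with BMP4, SCF, EGF and LIF, was measured as the difference between these libraries, and germ cell genes were higher in PGCLC of both origins. Prdm1, the repressor that sets germ cells apart, rose from 0.877 ± 0.223 to 39.6 ± 4.79 FPKM from ESC and from 1.18 ± 0.505 to 42.2 ± 7.48 FPKM from gPSC4, and its partner Tfap2c to 131 ± 8.44 and 135 ± 36.9 FPKM (SD, n = 3). Dppa3 rose to 1910 ± 115 and 1760 ± 84.7 FPKM. Genes of later germ cells that have reached the gonad rose as well, Dazl to 829 ± 100 and 793 ± 24.7 FPKM and Ddx4 to 230 ± 6.19 and 242 ± 31.8 FPKM. Hbb-y, an embryonic globin of red blood cells, rose from 0.901 ± 0.850 to 601 ± 47.8 from ESC and to 570 ± 62.6 FPKM from gPSC4, and Lhx9, a factor of the gonad's somatic cells, to 27.8 ± 1.58 and 33.2 ± 5.46 FPKM. Dnmt3b fell to 2.79 ± 2.10 and 3.72 ± 1.77 FPKM, and Fgf5 to 3.74 ± 1.46 and 6.41 ± 1.57 FPKM. From ESC the 6 highest were Hbb-y (8.40), Hba-a1 (8.30), Hba-x (7.93), Kctd14 (7.14), Tcl1 (7.07) and Fos (7.07), and from gPSC4 Dppa3 (7.28) took the place of Kctd14; Hba-a1 has a near-identical copy. Among the lowest from ESC were Dnmt3b (−7.43), Calca (−6.63), Pla2g1b (−6.23), Pim2 (−5.95) and Slc7a3 (−5.82), and from gPSC4 Pla2g1b (−6.88), Dnmt3b (−6.85), Calca (−6.19), Tmem54 (−5.72), Pmaip1 (−5.59) and Fgfbp1 (−5.43).

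Of 16 early germ cell genes 16 rose from ESC and 15 from gPSC4, among them Nanos3 (5.66 from ESC) and Prdm14 (5.01 and 5.40), and of 19 late germ cell genes 15 and 14 rose. Naive genes rose in 12 of 17 from each origin, Nanog by 3.51 and 3.54, and formative genes fell in 12 and 11 of 15. Of 17 blood and endothelial genes 13 and 14 rose, and of 18 genes of the fetal gonad's soma 15 and 14, such as Upk3b (5.27 and 5.41). Of 12 DNA methylation genes 6 and 7 fell, Dnmt3a among them (−3.19 from ESC). Of 19 glycolysis genes 9 fell from each, Ldha from 2220 ± 8.21 to 305 ± 20.9 and from 2320 ± 89.4 to 358 ± 10.5 FPKM, and fatty acid oxidation genes rose in 7 and 9 of 20. Targets of TGF-beta and BMP rose in 10 and 9 of 16, Id1 by 6.19 and 5.68. These 10 lists passed camera from both origins at adjusted p of 0.0051 or less and with an estimated correlation at 0.019 or less. Primitive endoderm genes were higher from ESC alone (0.015, 0.026 with an estimated correlation), a difference between origins that the test of the steps by origin did not call. In limma 2342 genes rose and 1780 fell from ESC, and 2215 rose and 1955 fell from gPSC4. The balance depended on scaling: rescaling to median ratios gave 2064 and 2006 from ESC and 1970 and 2161 from gPSC4, and quantile normalization 1974 and 2094 and 1985 and 2140. Across 14760 genes the changes had r 0.916.

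PGCLC of each origin were compared with PGC of E12.5, the stage at which germ cells have settled in the gonad. Dppa3 stood at 1930 ± 36.3 FPKM in PGC, Dazl at 862 ± 52.2, Ddx4 at 250 ± 15.4, Prdm1 at 43.4 ± 5.02 and Nanog at 243 ± 18.7 FPKM (SD, n = 3), and PGCLC of either origin lay within 0.24 log2 of each. Fgf4, a growth factor gene of pluripotent cells, was higher in PGCLC, at 12.4 ± 2.60 from ESC and 16.5 ± 6.49 from gPSC4 against 0.431 ± 0.207 FPKM. Spp1, a secreted matrix protein, was at 148 ± 31.6 and 263 ± 23.0 against 26.6 ± 4.09 FPKM, and Tdgf1, a co-receptor for Nodal, at 91.8 ± 30.3 and 150 ± 22.6 against 23.4 ± 0.252 FPKM. From ESC the highest were Fgf4 (3.22), Nrarp (2.76), Nupr1 (2.48), Spp1 (2.42), Klf9 (2.25) and Car4 (2.23), and Dnajc5g (−2.02), Bhlhe41 (−1.17) and Tmem143 (−1.16) were lower. From gPSC4 the highest were Fgf4 (3.55), Nupr1 (3.43), Spp1 (3.26), Fabp3 (2.63), Tdgf1 (2.62) and Mpzl2 (2.61), and Il7 (−2.67), Dnaaf5 (−2.48), Fst (−2.38), Iba57 (−2.17), Tmem39b (−1.84) and Ubald2 (−1.55) were lower.

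Of 14059 genes, limma called 48 higher and 12 lower in PGCLC from ESC, and 55 higher and 26 lower in PGCLC from gPSC4, with 1948 and 1848 at an unadjusted p under 0.05. Voom called 12 and 73. With only the groups compared in the fit, 0 and 8 genes were called, and 10 of 10 and 8 of 12 calls of the genes named above were lost. Groups did not overlap for 14.3% and 13.3% of the genes tested, where chance gives 10%. Of 16 early and 19 late germ cell genes 0 were called in either comparison. Naive genes were higher as a list (median 0.18 and 0.20, camera adjusted p 0.00024 and 8.2e-05) and held with an estimated correlation, at 0.026 and 0.0064. Adjusted over the list alone, 2 and 3 of 17 were higher, against 1 and 3 over all genes. Glycolysis genes were higher from gPSC4 (median 0.23, 4.9e-16, 0.0013 with an estimated correlation) and from ESC (median 0.10, 0.00024; adjusted p = 0.10 with an estimated correlation). Epithelial genes were higher from gPSC4 (0.00022, 0.0061 with an estimated correlation) and from ESC (0.022; adjusted p = 0.076 with an estimated correlation). From gPSC4, granulosa cell genes (0.016; adjusted p = 0.064 with an estimated correlation) and gonadal somatic genes (0.016; adjusted p = 0.081 with an estimated correlation) were lower and DNA methylation genes higher (0.016; adjusted p = 0.081 with an estimated correlation). Mean r between PGCLC and PGC libraries was 0.975 from ESC and 0.973 from gPSC4, and 0.979 among PGC libraries. The counts moved when 1 library was left out, to 140 without ESC-PGCLC replicate 1, 29 without ESC-PGCLC replicate 3, 26 without PGC replicate 2 and 39 without PGC replicate 3 for PGCLC from ESC, and to 148 without gPSC4-PGCLC replicate 3 for PGCLC from gPSC4.

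Whether the steps themselves differed by origin was tested as a difference of differences. In the EpiLC step 2 genes were called, both higher from gPSC4 (663 at an unadjusted p under 0.05, 1 by voom). They fell outside the rule for named genes and were looked up after their values were seen. Cmtm5 was listed at 0 apart from 2.82 ± 1.03 FPKM in gPSC4-EpiLC, and Gm5878, a predicted gene, stood at 4.65 ± 2.32 FPKM in gPSC4-EpiLC and 0.38 ± 0.66 FPKM in ESC-EpiLC. Quantile normalization gave 2 higher and 1 lower, and 4 genes were called without gPSC4-EpiLC replicate 3. Targets of TGF-beta and BMP were lower as a list (median −0.20, camera adjusted p 0.011; adjusted p = 0.053 with an estimated correlation), and X- and Y-linked genes higher (median 0.20, 0.04; adjusted p = 0.11 with an estimated correlation). In the PGCLC step 7 genes were higher and 5 lower from gPSC4, 7 and 2 after quantile normalization, with 1627 at an unadjusted p under 0.05 and 1 by voom. The count was 43 without gPSC4-PGCLC replicate 3, and 20 or 21 without ESC-PGCLC replicate 1 or 2. Chst11, a chondroitin sulfotransferase gene, rose from 1.75 ± 0.225 to 6.23 ± 1.06 FPKM from gPSC4 and went from 3.54 ± 0.533 to 1.34 ± 0.427 FPKM from ESC (difference 2.35 ± 0.34 SE, limma adjusted p 0.008). Trh (1.64), Fam53b (1.47) and Vhl (1.22) followed. Cited2, a transcriptional co-regulator, was at 10.3 ± 4.00 then 2.16 ± 1.35 FPKM from gPSC4 and at 5.55 ± 1.84 then 9.84 ± 4.10 FPKM from ESC (−2.57 ± 0.48), and Btg3 differed by −2.33. No list was called in the PGCLC step (0 of 26 tested), and no germ cell gene named above was called in either step.

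The Y-linked genes named above were measured in the induction set too. Their summed level was 5.45 ± 0.156 FPKM in ESC, a female line, 1.08 ± 0.442 in ESC-EpiLC and 9.33 ± 2.90 FPKM in ESC-PGCLC, and 3.72 ± 0.846, 0.61 ± 0.537 and 11.1 ± 1.03 FPKM at the same stages from gPSC4 (SD, n = 3). In PGC it was 9.16 ± 1.32 FPKM. Eif2s3y rose in the PGCLC step from both origins (2.09 and 2.61, limma adjusted p 1.4e-06 and 7.1e-08), as did Uty (1.22 and 1.09). These genes have relatives on the X chromosome that share part of their sequence, yet the sum was 0.07 FPKM in the granulosa cells of the lines' table and 0 in those of the ES table.

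**Figure D5:**
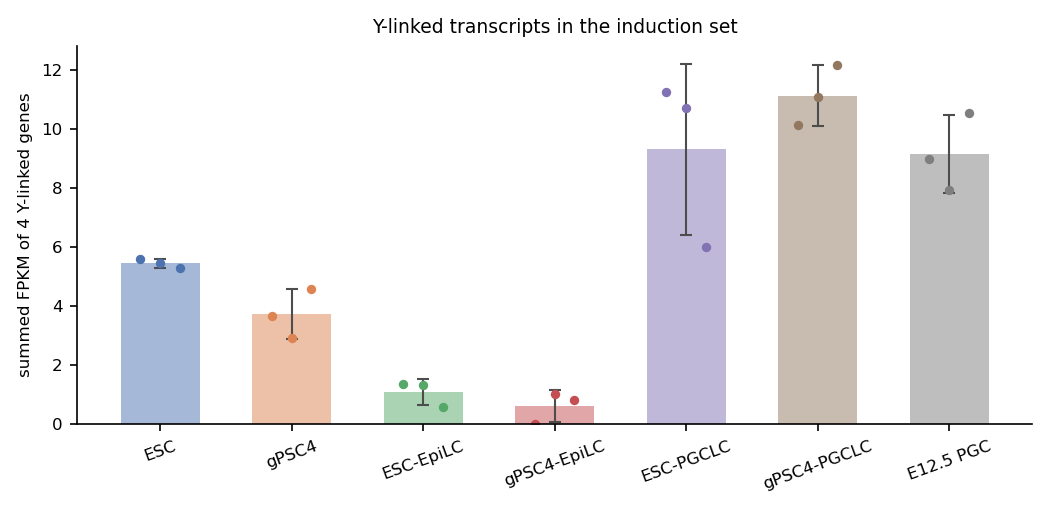
Summed FPKM of Ddx3y, Uty, Kdm5d and Eif2s3y in the induction set; bars are means, error bars SD and points libraries (n = 3 per group). PGCLC of both origins were near PGC, at 9.33, 11.1 and 9.16 FPKM, and EpiLC lowest, at 1.08 and 0.61 FPKM.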

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

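Steps that differed by origin were picked out by a rule set before the data were examined, and the lookup of Cmtm5 and Gm5878 was chosen after their values were seen. In the EpiLC step, Cmtm5 differed by 1.89 log2 and Gm5878 by 3.64 between gPSC4 and ESC. In the PGCLC step the differences were 2.35 for Chst11, 1.64 for Trh, 1.47 for Fam53b, 1.22 for Vhl, −2.57 for Cited2 and −2.33 for Btg3. Cmtm5 and Gm5878 kept their calls in each fit with 1 library left out, while 2 of the 6 genes of the PGCLC step lost theirs in at least 1 such fit. With voom on recovered reads, 0 of these 8 genes were called. Divisions of the libraries gave as many genes in 3 of 100 for the EpiLC step (real count 2, highest other 2) and in 2 of 100 for the PGCLC step (real count 12, highest other 27), the real ones included. These shares are low, but other divisions equalled or exceeded the real counts, so chance is not excluded in either step. The division that called 27 genes mixed both origins at each stage, with 1 of 3 gPSC4 libraries under its own origin. Whether these libraries hold a structure besides origin was not tested.

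Each of the 6 gPSC lines was also compared with the rest for the genes named in the lines, the correlation with ES cells, the Y-linked level and the share of fibroblast transcripts. Chance flags about 1 in 20 groups of 6, and of 37 sets of values 0 had a line set apart. A pair of lines that stand apart together escapes this comparison. Lines 2 and 10, seen only afterwards, had r 0.996 with each other and 0.983 to 0.990 with the other lines, while lines 4 and 16 also had r 0.996. Their fibroblast share was 22.6% and 19.8% (11.4% to 13.9% in the others), their Y-linked level 4.54 and 4.05 FPKM (2.26 to 2.95) and Dppa3 9.27 and 4.51 FPKM (21.5 to 30.3), without a test.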

How the results depend on the processing

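Of the settings below, voom on recovered reads and the length correction were chosen after results had been seen. Results that moved are given by setting, and the cause was not tested except for the minimum difference, which can add genes by construction.

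Without a minimum log2 difference, the number of genes called was 957 for crotonic acid, 2985 for day 28 against day 16, 9988 for lines against granulosa cells, 4, 26 and 84 for gPSC4 against ESC as stem cells, EpiLC and PGCLC, 6426 and 6300 for the EpiLC steps from ESC and gPSC4, 8072 and 8199 for the PGCLC steps, and 119 and 149 for PGCLC against PGC. A pseudocount of 0.1 gave 1125 genes for day 28 against day 16. Without a filter on low values there were 3 genes for gPSC4 against ESC, 38 for ESC-PGCLC against PGC and 4 for the EpiLC step by origin. Without a trend the counts were 28 for PGCLC by origin, 37 for ESC-PGCLC against PGC and 4 for the EpiLC step by origin. With only the groups compared in the fit, they were 0, 2 and 0 for gPSC4 against ESC at the 3 stages, 0 and 8 for PGCLC against PGC, and 4 and 4 for the steps by origin. Voom on recovered reads gave 2 for EpiLC and 22 for PGCLC by origin, 12 for ESC-PGCLC against PGC, and 1 and 1 for the steps by origin. After the length correction, day 28 against day 16 had 470 genes higher and 132 lower.

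With 1 library left out, counts ranged from 7 (without D28CA replicate 1) to 25 (without D28CA replicate 2) for crotonic acid, from 518 to 1147 (without XEN16D replicate 2) for day 28 against day 16, and from 5371 to 5558 for lines against granulosa cells. For gPSC4 against ESC the range was 0 to 3 as stem cells, 4 to 10 as EpiLC and 29 to 157 as PGCLC. It was 2839 to 2912 and 2792 to 2890 for the EpiLC steps, 4056 to 4176 and 4057 to 4218 for the PGCLC steps, 26 to 140 and 69 to 148 for PGCLC against PGC, 2 to 4 for the EpiLC step by origin and 8 to 43 for the PGCLC step by origin.

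The difference between the correlations of day 16 cells with granulosa cells and with fibroblasts was 0.068 without a filter and 0.178 at a filter of 10 FPKM, with a range of 0.096 to 0.113 over libraries left out. Line 4 ranked 3 by its correlation with ES cells, and 2 without line 11 or 16. The change from granulosa cells to lines and to ES cells correlated at 0.927 by Spearman's rho and 0.95 at 10 FPKM (0.937 to 0.94 over libraries left out). The EpiLC step correlated across origins at 0.89 by Spearman's rho, 0.893 with a pseudocount of 0.1 and 0.961 at 10 FPKM (0.923 to 0.932). The PGCLC step did so at 0.869, 0.875 and 0.944 (0.898 to 0.914).

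There were 108 list calls over 14 comparisons in the main setting and 54 with an estimated correlation, each counted over all lists tested. The number was 106 with a pseudocount of 0.1, 115 without a filter, 112 after median-ratio rescaling and 105 after quantile normalization. Of 227 calls of named genes, 46 were lost in at least 1 fit with a library left out, 16 with a pseudocount of 0.1, 11 without a filter, 10 without a trend, 6 after quantile normalization and 4 after median-ratio rescaling. In the fits that covered fewer of them, 39 of 194 were lost with only the groups compared and 30 of 136 with voom, and 0 changed direction under any setting.

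Using the replicate number as a block gave 6 genes for EpiLC by origin, 88 for PGCLC by origin and 98 for ESC-PGCLC against PGC, and 76 list calls over 10 comparisons where 72 were called without it. Whether equal numbers mark a pairing is not stated. Deviations of libraries with equal numbers from their group means correlated at 0.136 to 0.338 in the reprogramming set, which has 2 libraries per group. In the induction set the range was 0.006 to 0.172 between groups other than PGC and −0.028 to 0.023 with PGC. Equal numbers were the best match throughout the reprogramming set, where with 2 libraries per group that means only a positive correlation. They were also the best match in most cases outside PGC in the induction set. This points to a shared deviation that the main fits leave out. No paired analysis was possible because the ESC columns of that set carry no number, which covers the comparisons with them, and lines against granulosa cells had 1 granulosa cell library. An analysis from raw counts was not run, as no raw counts were used here, and the settings without a trend or a minimum difference do not apply to the correlations.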

Other observations

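The tests in this part were chosen after the patterns had been seen, apart from the other divisions of the libraries in the last paragraph. Each explanation is a hypothesis, since it was found and tested on the same data.

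PGCLC libraries lay at the level of PGC libraries. Of 84 divisions of the 9 libraries only the real one, 1 in number, called as many as 6 genes (highest other 3), so PGC stood apart from PGCLC. Libraries of one kind that were prepared apart could differ in this way too. The divisions therefore cannot decide whether all 9 libraries are of one kind under different labels. An exchange of PGC and PGCLC columns as the source of the Y-linked level is argued against, since it would leave 2 of the 3 groups from female lines, and the lowest of the 9 libraries stood at 5.99 FPKM against at most 1.35 FPKM in EpiLC. The PGCLC libraries may hold RNA of male cells, as the summed Y-linked level was 9.33 FPKM in PGCLC of the female ESC line and 1.08 FPKM in its EpiLC, and RNA of blood and gonadal somatic cells, whose blood genes lay a median 0.16 log2 (SD 0.29 over 17 genes) from PGC and 3.39 above EpiLC. Of these 17 genes 3 reached 1 FPKM in ESC-EpiLC, and Hbb-y, the most abundant, stood at 601 FPKM. Whether RNA of pluripotent cells adds to the difference from PGC stays open. Over 26 genes the median excess over PGC was 3.08% of the gPSC4 stem cell level (lower quartile 0.636%) and 1.14% of the ESC level (lower quartile 0.179%). These genes reached 100 FPKM in the stem cells and averaged at most 5% of their stem cell level over the 9 PGC and PGCLC libraries. As PGCLC libraries entered that filter, it limited the excess in advance, and the values do not estimate a share. A sort for germ cells would bear on RNA of male, blood, gonadal somatic and pluripotent cells alike. Wrong labels that involve other samples, and a culture together with gonadal cells, were not tested and stay open, so the step from EpiLC to PGCLC need not be the product of the induction alone.

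Fibroblast and Y-linked transcripts occurred in pluripotent libraries of female origin. RNA of feeder fibroblasts may be the source of the fibroblast transcripts in the ES libraries and the lines, since 28 genes abundant in fibroblasts and low in granulosa cells stood at a median of 13.4% of the fibroblast level in each ES library and 11.4% to 22.6% in the lines. Whether H19 and Igf2, which rose in the lines, have that source was not tested. Igf2 stood at 126 to 275 FPKM in the lines and at 60.9 and 61.6 FPKM in the ES libraries. Line 11, at 126 FPKM, had a lower fibroblast share than the ES libraries. Among the lines, Igf2 was highest in lines 2 and 10 (275 and 262 FPKM), as was H19 (352 and 346 FPKM). Lines 2 and 10 also had the highest fibroblast shares, 22.6% and 19.8%. Lines and ES libraries lay in separate tables, so these values cannot decide whether feeders account for Igf2. Of the fibroblast list, 11 genes also reached 5 FPKM in the granulosa cells of the lines' table. In the induction set this stays open, as the share was 3.77% in ESC and 3.13% in gPSC4, with 4 to 7 of 28 genes under 1%, and so does the source of the fibroblast genes that fell in the EpiLC step, where the share went to 0.448% and 0.332%. Whether feeders bring the Y-linked transcripts stays open as well, because 1 fibroblast library had none and the other 22.5 FPKM. In percent of that library, the lines stood at a mean of 14.2% for the Y-linked level and 18.3% for the fibroblast genes. ES libraries stood at 28.8% against 13.2%, ESC at 24.2% against 4.54% and gPSC4 at 16.5% against 3.45%. In these the Y-linked share exceeded that of the fibroblast genes. Each share divides levels of one table by a fibroblast library of another table. In the lines' table, line 4 stood at 13.1% for the Y-linked level and 16.7% for the fibroblast genes. That order is the reverse of gPSC4 in the induction set. Whether the excess in the induction set comes from the cells or the tables therefore cannot be decided. The fibroblast library used here also had Xist at 11.3 FPKM, so it may hold cells of both sexes. Feeders with more male cells would give a higher Y-linked level than it does. That ESC and gPSC4 cells are themselves male is argued against, as 19.8% of the Y-linked level was left in EpiLC from ESC and 16.4% in those from gPSC4. A removal of feeders before lysis would bear on both.

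Endoderm and epithelial lists were higher and the oxidative phosphorylation list lower at day 28 than at day 16 (adjusted p = 0.34, adjusted p = 0.38 and adjusted p = 0.38 with an estimated correlation, so none of these calls held), while replicates 1 and 2 differed by transcript length in the same direction in each of the 3 groups (rho −0.70, −0.46 and −0.54). A length trend as the whole cause is argued against for the endoderm and epithelial lists, whose medians after the correction were 0.74 and 1.06 with all genes at 0.01. For oxidative phosphorylation the trend could account for part, as the median went from −0.40 to −0.22, to −0.17 without XEN16D replicate 1 and to −0.14 after quantile normalization. It was −0.63 without XEN16D replicate 2. Measured from the median of all genes, the list stood at −0.54 in the main fit and −0.23 after the correction. That distance was −0.27 without XEN16D replicate 1 and −0.84 without replicate 2, so this part stays open. Median-ratio rescaling, which moves nearly all genes alike, left the distance at −0.57 and does not bear on length.

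With 3 libraries against 3 there are 10 divisions, too few for a share under 0.05, and in each comparison the real one, 1 in number, gave more genes than any other. The other divisions mix both groups, which lowers the difference and raises the spread. For the EpiLC and PGCLC steps, where many genes differed, this outcome was therefore fixed in advance. The real count and the highest other were 1 and 0 for gPSC4 against ESC, 10 and 2 as EpiLC, 44 and 23 as PGCLC, 2947 and 0 and 2874 and 0 for the EpiLC steps from ESC and gPSC4, 4122 and 8 and 4170 and 2 for the PGCLC steps, and 60 and 10 and 81 and 17 for PGCLC against PGC.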
